A study of Caenorhabditis elegans with 4 samples.

How the data were processed

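Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on young adult hermaphrodites of Caenorhabditis elegans strain OP429, which carries a transgene for the protein F23B12.7 fused to GFP and a FLAG tag. Per the labels' protocols, synchronised worms were grown at 20 °C on plates of E. coli, crosslinked in 2% formaldehyde and sonicated. A portion of the lysate (10%) was kept as input, which is total genomic DNA carried through the same steps, and the rest was precipitated with an anti-GFP antibody. The labels give 2 ChIP samples and 2 input samples, numbered 1 and 2 in each group. Nothing in the labels says whether the numbers mark separate cultures, so the spread between replicates may be technical.

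The data used here are 3 lists of called regions: a list for ChIP replicate 1, a list for ChIP replicate 2, and a combined list for the series. The authors called the regions with PeakSeq, per the file contents, and deposited a q-value for each region, which is the only measurement in the lists. Per the file headers, coordinates are on WormBase build WS180. PeakSeq finds stretches with many ChIP reads and then compares them with a scaled input library, so a q-value depends on read depth, on the scaling of the input and on the width of the stretch, and is not a fold enrichment. The aligner, the PeakSeq version, the q limit, the input library behind each list and the way the combined list was made are not given in the sources used here. Read counts, coverage and the input libraries were not analysed here, and the sequencing depth of each sample is unknown. The q-value in the score column and the one in the attribute column, compared as parsed numbers with no tolerance, were identical for all 2621, 1038 and 310 regions of the combined, replicate 1 and replicate 2 lists. No region overlapped another within its own list.

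Samples were grouped by their titles. ChIP against input was therefore read only through the authors' calls, and the comparisons made here were between region lists. Regions of 2 lists were counted as shared when they overlapped by at least 1 bp. The number shared was compared with 10000 random placements of the regions within their own chromosome (one-sided permutation test, smallest possible p = 0.0001), which ignores mappability and open chromatin. Agreement of q-values was measured by Spearman's rho of −log10 q over regions paired 1 to 1 by largest overlap, with 100000 permutations (two-sided, smallest possible p = 1e-05). The share of combined regions overlapped by a replicate list was taken by quartile of q-value and tested by Fisher's exact test. Regions per chromosome were compared with chromosome length by two-sided exact binomial tests with Benjamini-Hochberg adjustment over 6 chromosomes, and the share of midpoints in the central 33.3% of a chromosome by an exact binomial test against that share. Chromosome lengths were not in the lists, so the furthest region end on each chromosome in any list stood for its length, from 13.8 Mb for chromosome III to 20.8 Mb for chromosome V and 100.1 Mb in all. Median widths were compared by permutation. Intervals are 95% Wilson intervals and cover counting error only. Tests across regions treat regions as independent, which neighbouring regions are not.

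Before the data were examined, the 20 regions with the lowest q-values in the combined list and the 5 with the lowest in each replicate list were chosen as the ones to name, together with genes near them, the tagged gene F23B12.7 and unc-119. The annotation at hand belongs to another build (WBcel235), so its coordinates were not set against the WS180 regions. Gene starts, the fixed gene lists, sequence motifs and the expectation from genes per chromosome were therefore not analysed here, and regions are named by position. Alternatives fixed at the same time were a stricter overlap, midpoints within 100 bp, the better-scored 50% of a list, placement within 100 kb, and each replicate list alone.

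The tests were tried on simulated data, with fewer placements or permutations than the real tests used. In the simulations of overlap and of chromosomes, lists had about the sizes of the real ones. Their regions were drawn independently of one another, as those tests assume. They had no clustering and no shared mappability or open chromatin, so these rates do not show how often the tests err on real lists. Of 50 pairs of unrelated replicate lists, 0 had an overlap p under 0.05, and of 50 pairs that shared 31 of the 310 replicate 2 regions, 50 did. With chromosome I thinned to 0.75 of its share of 2621 regions, 198 of 200 simulated lists gave an adjusted p under 0.05 for it, against 2 of 200 uniform lists. The test of q-values within strata of width called 0 of 30 simulations without a shift and 20 of 30 with a shift of 0.5 on the −log10 scale. These simulations shuffled the autosomal q-values of the combined list, so they give no rate for the shorter replicate lists. The test of rank agreement called 1 of 30 simulations of unrelated values and 30 of 30 with a correlation of 0.5, and the test of median widths called 3 of 30 simulations without a shift and 30 of 30 with a shift of 60 bp. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.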

Results

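Genomic regions enriched over input in anti-GFP ChIP-seq of GFP-tagged F23B12.7 were called in young adult C. elegans hermaphrodites. As background that the labels do not give, F23B12.7 is the worm relative of human CEBPZ, a protein of the CCAAT-binding factor family. Whether the called regions hold CCAAT sequences was not tested. The study has 2 ChIP samples and 2 input samples. No ChIP sample came from worms without the tagged protein. Signal that does not depend on that protein therefore cannot be told apart from its binding, and it could recur in both replicates. The combined list held 2621 regions, with a median width of 371 bp and a range of 23 to 4449 bp. ChIP replicate 1 gave 1038 regions with a median width of 373 bp, and ChIP replicate 2 gave 310 regions with a median width of 394.5 bp. Replicate 1 thus had 3.35 times as many regions as replicate 2. The called regions covered 1.20%, 0.482% and 0.150% of the genome length in the combined, replicate 1 and replicate 2 lists. All q-values are the authors' own, one per region and list. The weakest q-value was 2.59e-04 in the combined list, 1.36e-04 in replicate 1 and 4.51e-05 in replicate 2. The read depth behind these lists is unknown.

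The first question was where the anti-GFP ChIP signal was enriched over input, as called by the authors. The region with the lowest q-value in all 3 lists lay at the right end of chromosome I, from 15064011 to 15067636 in the combined list, with q = 6.81e-264. It was called at 15064018 to 15067635 in replicate 1 (q = 4.98e-201) and at 15064018 to 15067609 in replicate 2 (q = 1.88e-105). No region of any list reached further along this chromosome. The tandem ribosomal DNA repeats of this species lie at the right end of chromosome I, and whether the called region falls within them was not tested here. On the −log10 scale the q-value of this region was 263, against 64.8 for the second region of the combined list, and the same gap was 200.3 against 43.4 in replicate 1 and 104.7 against 20.9 in replicate 2. A q-value falls with the number of reads as well as with enrichment, so this gap does not measure how strongly the protein binds there.

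All 20 regions with the lowest q-values in the combined list were also called in both replicates. Of these, 2 lay on chromosome I, 5 on II, 4 on III, 2 on IV, 2 on V and 5 on X. They fell into broad and narrow regions, with 9 wider than 2000 bp, 9 narrower than 1000 bp and 2 in between. Regions wider than 2000 bp numbered 18 in the whole combined list. The broad regions after the one at the end of chromosome I began with chromosome X from 16929208 to 16931882 (q = 1.70e-65), which ranked 2 in replicate 1 and 5 in replicate 2. Chromosome V from 723959 to 728265 (q = 3.71e-58) and from 14685590 to 14688792 (q = 5.46e-42) ranked 4 and 5 of 1038 in replicate 1 and 48 and 58 of 310 in replicate 2. Replicate 1 called the former as 2 regions of 3216 and 961 bp and the latter as 1 region of 3221 bp. Replicate 2 called 1 region of 1243 bp in the former and 2 of 563 and 506 bp in the latter. Ranks are those of the best replicate region inside each combined region, and 5 of the 9 broad regions were called as 2 regions in at least 1 replicate. Chromosome III from 8443599 to 8447305 (q = 1.45e-53) ranked 16 in replicate 1 and 6 in replicate 2. On chromosome II, the regions from 8743129 to 8747577 (q = 8.31e-39), from 6345824 to 6349037 (q = 2.05e-37) and from 10541826 to 10544216 (q = 3.90e-35) were of this kind, as was chromosome I from 7656574 to 7659383 (q = 1.58e-33). The last of these ranked 22 in replicate 1 and 4 in replicate 2.

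The narrow regions among the 20 were led by chromosome IV from 654686 to 655127, 442 bp wide with q = 2.30e-36, which ranked 8 in replicate 1 and 7 in replicate 2. Chromosome X held 4 of them, from 8036048 to 8036883 (q = 2.86e-31), from 11093869 to 11094363 (q = 4.30e-28), from 806433 to 806913 (q = 7.02e-28) and from 2996730 to 2997389 (q = 7.36e-28). The last of these ranked 3 in replicate 2, at q = 2.26e-16, and 9 in replicate 1. Chromosome III held 2, from 8043714 to 8044171 (q = 4.42e-29) and from 10758925 to 10759532 (q = 1.38e-28). The remaining narrow regions were chromosome II from 10563017 to 10563666 (q = 2.66e-28) and chromosome IV from 4749867 to 4750232 (q = 3.12e-27). The 2 regions of intermediate width were chromosome III from 3866727 to 3867998 (q = 2.74e-42) and chromosome II from 5543284 to 5544502 (q = 2.28e-27). The former ranked 3 in replicate 1 and 2 in replicate 2. All 5 regions with the lowest q-values in each replicate list overlapped a region of the other replicate.

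The second question was how far the replicates called the same regions. Of the 310 regions of replicate 2, 252 overlapped a region of replicate 1, which is 81.3% (95% Wilson interval 76.6 to 85.2%). Random placement gave a mean of 3.37 overlaps and at most 12, so the observed number was 74.7 times the mean (permutation p = 0.0001, the smallest possible). In the other direction, 252 of 1038 replicate 1 regions overlapped replicate 2, or 24.3% (21.77 to 26.98%). When replicate 1 was shortened to its best 310 regions, 164 of the 310 replicate 2 regions (52.9%) overlapped it, again far above placement (mean 1.21, permutation p = 0.0001). This comparison of equal lengths was chosen after the data were seen.

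Over 251 paired regions, −log10 q correlated between the replicates with Spearman's rho of 0.49 (permutation p = 1e-05, across regions, which are not independent replicates). The q-value was lower in replicate 1 for 188 of the 251 pairs (74.9%), with a median −log10 q of 7.12 in replicate 1 and 5.63 in replicate 2. Shared regions had lower q-values than unshared ones in both lists. In replicate 1 the median −log10 q was 7.11 for shared and 4.94 for unshared regions (difference 2.17, permutation p = 1e-05), and in replicate 2 it was 5.65 and 4.83 (difference 0.82, permutation p = 0.00164). Each list is cut by q-value, and a region near the end of one list easily misses the other. The direction of these differences is therefore largely built in. The regions of replicate 1 with the lowest q-values and no counterpart in replicate 2 were chromosome V from 9342936 to 9344590 (q = 4.33e-15), chromosome III from 12425825 to 12426775 (q = 6.84e-14) and chromosome II from 11634072 to 11635957 (q = 5.36e-13). In replicate 2, the region with the lowest q-value and no counterpart in replicate 1 was chromosome II from 10033246 to 10033759, at q = 1.55e-07. These 4 regions were picked after their values were seen, and each overlapped a region of the combined list.

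**Figure D1:**
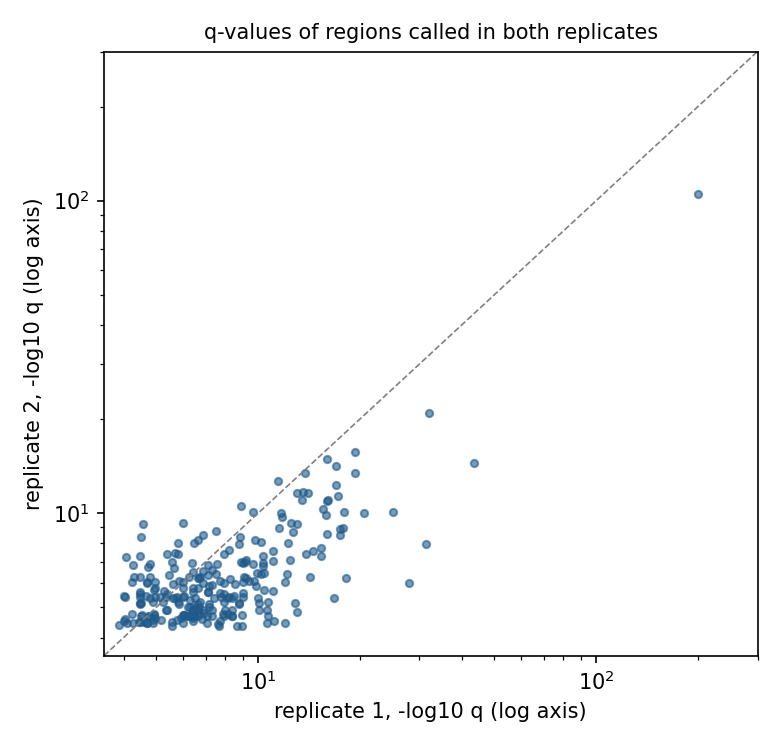
Each point is 1 of the 251 regions paired between the replicates, with −log10 q in replicate 1 on the x axis and in replicate 2 on the y axis, both on log axes, and the dashed line marking equal values. Most points (188) lie below the line, and the region at the right end of chromosome I stands apart at 200.3 and 104.7.

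The third comparison set the combined list beside the replicate lists. The combined list contained nearly all replicate regions, with 1005 of 1038 from replicate 1 (96.8%, 95.6 to 97.7%) and 308 of 310 from replicate 2 (99.4%, 97.7 to 99.8%). Conversely, 1056 of the 2621 combined regions (40.3%, 38.4 to 42.2%) overlapped at least 1 replicate list. Both replicates called 248 of them, replicate 1 alone 752, replicate 2 alone 56, and neither 1565 (59.7%). In 244 of the 248 combined regions called in both replicates (98.4%, 95.9 to 99.4%), the combined q-value was lower than both replicate q-values.

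Overlap with the replicates fell steeply with the q-value of the combined region. In the quartile with the lowest q-values, 581 of 656 regions (88.6%, 85.9 to 90.8%) were called in at least 1 replicate, followed by 47.2%, 18.02% and 7.33% (5.57 to 9.58%) in the next quartiles. The odds ratio between the first and the last quartile was 97.96 (Fisher's exact test, p = 6.42e-220). If the combined list rests on the same reads as the replicate lists, which the sources do not state, its weak regions would be expected to drop out of lists made from fewer reads, so this fall is not independent support for the stronger regions. Replicate 1 overlapped 84.8% of the first quartile and 6.41% of the last, and replicate 2 overlapped 39.8% and 1.07%. With midpoints within 100 bp instead of any overlap, 34.5% of all combined regions had a counterpart.

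**Figure D2:**
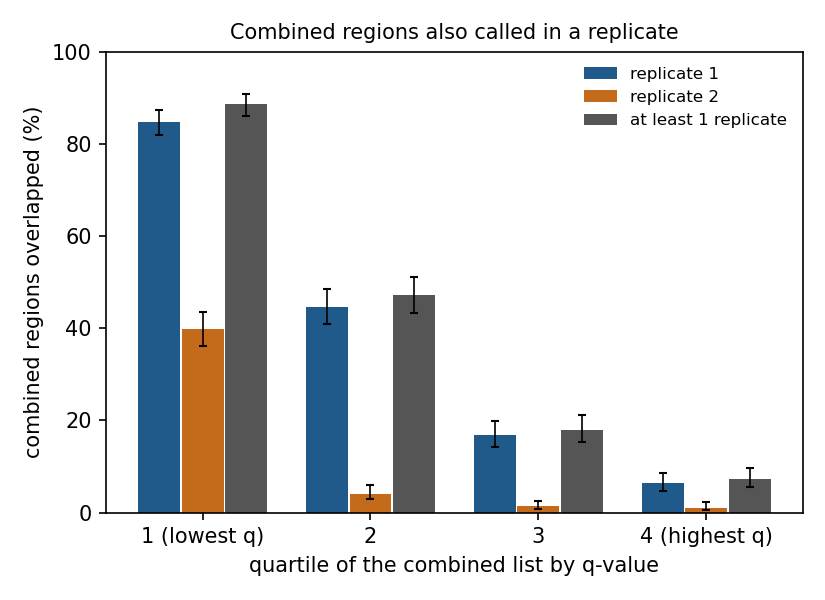
Bars give the percentage of combined regions overlapped by replicate 1, by replicate 2 and by at least 1 of them, in quartiles of the combined list from the lowest to the highest q-values, and error bars are 95% Wilson intervals. The share called in at least 1 replicate falls from 88.6% in the first quartile to 7.33% in the last.

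The regions were unevenly spread over the chromosomes. Chromosome III held 579 of 2621 combined regions, or 42.1 per Mb, which was 1.61 times the number its length predicts (exact binomial test, adjusted p = 3.45e-30). Chromosome II was also above its length, with 482 regions and a ratio of 1.21 (exact binomial test, adjusted p = 1.25e-05). The X chromosome was lowest, with 332 regions, 18.7 per Mb and a ratio of 0.72 (exact binomial test, adjusted p = 7.54e-12). Chromosome I had 311 regions and a ratio of 0.79 (exact binomial test, adjusted p = 4.40e-06), and chromosome V had 435 regions and a ratio of 0.80 (exact binomial test, adjusted p = 9.25e-08). The 482 regions of chromosome IV gave a ratio of 1.05, which did not pass the test (exact binomial test, adjusted p = 0.207).

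Each replicate list showed the same directions on all 6 chromosomes. For chromosome III the ratio was 1.63 in replicate 1 and 1.92 in replicate 2, and for the X chromosome it was 0.70 and 0.69. Chromosome I lay lower in the replicate lists than in the combined list, at 0.58 in replicate 1 (90 regions) and 0.43 in replicate 2 (20 regions). Its share was 8.67% (7.11 to 10.5%) of replicate 1 regions and 6.45% (4.21 to 9.75%) of replicate 2 regions (Fisher's exact test, p = 0.238). That test takes the lists as independent, but 252 of the 310 replicate 2 regions overlapped replicate 1, so it cannot settle whether the share differed. Of the 90 replicate 1 regions on chromosome I, 14 (15.6%, 9.50 to 24.4%) overlapped replicate 2. On the other chromosomes this percentage ran from 21.9% (X) to 29.7% (III), a contrast that was not tested. The excess of chromosome II did not pass the test in replicate 2 alone, with a ratio of 1.25 (exact binomial test, adjusted p = 0.0823). Lengths were taken from the furthest called region, and gene density was not accounted for.

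**Figure D3:**
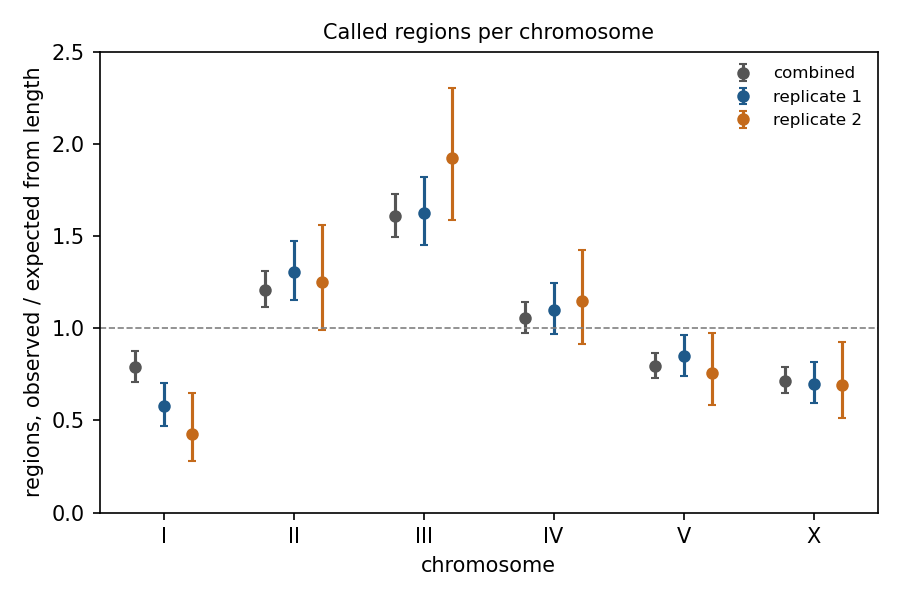
For each chromosome on the x axis, points give the number of called regions divided by the number its length predicts, for the combined, replicate 1 and replicate 2 lists, with error bars from the 95% Wilson interval and the dashed line at a ratio of 1. Chromosome III lies above the line in all 3 lists, and chromosomes I, V and X lie below it.

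Regions were more frequent in the central part of the chromosomes than in the outer parts. Of the 2621 combined regions, 1047 had their midpoint in the central 33.3% of the chromosome, or 39.9% (38.1 to 41.8%) of regions (exact binomial test, p = 1.48e-12). All 5 autosomes passed the test, from 39.6% on chromosome IV (adjusted p = 0.0056, exact binomial test) to 42.5% on chromosome V (adjusted p = 4.16e-04, exact binomial test). On the X chromosome, 111 of 332 regions (33.4%, 28.6 to 38.7%) lay in this central part. This was less than the 936 of 2289 (40.9%) on the autosomes (Fisher's exact test, p = 0.0099). The comparison of X with the autosomes was not among the planned analyses, and X was the only chromosome that did not pass the binomial test. The share was 40.6% in replicate 1 (exact binomial test, p = 1.24e-06) and 38.1% in replicate 2, where it did not pass the test (exact binomial test, p = 0.0807). Gene density along the chromosomes was not accounted for, so neither the central excess nor its absence on X can be read as a preference of the protein.

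Over the whole lists, median region width did not differ detectably between the replicates. Widths were not compared within the regions paired between the replicates, so a difference at the same positions stays open. The median was 21.5 bp larger in replicate 2 than in replicate 1 (two-sided permutation test, p = 0.062). The direction turned when lists of equal length were compared, an alternative chosen after the data were seen. The best 310 regions of replicate 1 had a median width of 453 bp, and replicate 2 was then narrower (replicate 2 minus replicate 1, −58.5 bp, permutation p = 2.60e-04). Only replicate 1 was cut by q-value, and its regions with lower q-values were wider, so this p-value cannot separate the cut from a difference between the replicates. Wider regions had lower q-values in every list, with a Spearman's rho between width and −log10 q of 0.50 in the combined list, 0.40 in replicate 1 and 0.34 in replicate 2 (permutation p = 0.0001 for each, across regions).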

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

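Of 33 alternatives to the results above, 28 fixed before the data were examined and 5 added afterwards, 30 kept the direction and the side of the threshold. Most of the 33 recompute chromosome ratios or central shares on part of the combined list or on a replicate list. The combined list contains 96.8% of replicate 1 and 99.4% of replicate 2 regions, so these alternatives are not independent of the main results. Chromosome IV counts as kept because it did not pass in any list. The excess of regions shared by the replicates stayed above random placement under a stricter overlap, midpoints within 100 bp, the better-scored 50% of each list, placement within 100 kb and lists of equal length, at 49.5 to 257 times the mean. With midpoints within 100 bp the share of combined regions with a counterpart in a replicate fell from 40.3% to 34.5%, and with 1 replicate list at a time it ranged from 11.6% (replicate 2 alone) to 38.2% (replicate 1 alone). The ratio for chromosome II ranged from 1.25 to 1.30 and the share in the central part of the chromosomes from 38.1% to 40.6% over the replicate lists taken alone, and both lost the call in replicate 2, whose list has 310 regions in place of 2621. The ratio for chromosome I moved by more than 1.5 times, from 0.79 to 0.43, with the replicate 2 list alone, which keeps 20 regions there. The difference in median width between the replicates, 21.5 bp and not past the threshold, reversed to −58.5 bp with lists of equal length, since the weaker and narrower regions of replicate 1 then drop out. No paired analysis was possible because the input libraries were not analysed here and each ChIP sample is a single list of regions. Results that need an annotation or a genome sequence of build WS180 (gene starts, gene lists, motifs and the expectation from genes per chromosome) were not run. With no read counts, the part of the 3.35-fold difference in the number of regions between the replicates that comes from depth cannot be measured. The lists also end at different q-values, 1.36e-04 in replicate 1, 4.51e-05 in replicate 2 and 2.59e-04 in the combined list. They were not cut at a common q-value, so the part of the counts and overlaps that comes from these unlike ends was not measured.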

Other observations

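Several tests in this part were chosen after the data had been seen. They include the comparison of neighbouring regions within 5000 bp with local placements and the shift applied to the other autosomes. They also include the values per chromosome at matched width, the replicate regions inside broad combined regions and the comparison of q-values on X. The weighing of the replicate 2 list for X was chosen then too. The width contrast between X and the autosomes and the matched-width test of chromosome I also started from patterns already seen in the lists. Neither was among the planned analyses.

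Regions of the combined list lay close to one another more often than placement gave, with 596 of 2615 pairs of neighbouring midpoints (22.8%) within 5000 bp. Local placement within 100 kb gave a mean of 382 and at most 449 such pairs (permutation p = 0.0001, the smallest possible). A candidate explanation is that PeakSeq split single broad signals into several regions. Pairs 2000 to 5000 bp apart were also in excess, with 334 against a mean of 220.8 and a maximum of 273 (1.51 times, permutation p = 0.0001), which argues against splits of signals under 2000 bp as the whole cause. Splits of wider signals stay open, since 5 of the 9 regions wider than 2000 bp among the 20 with the lowest q-values were called as 2 regions in at least 1 replicate, with midpoints up to 2691 bp apart. Local differences in gene density or mappability were not tested.

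Chromosome I had 20.6 called regions per Mb in the combined list, a ratio of 0.70 to the 29.4 per Mb of the other autosomes pooled, but chromosome V was as low in this list at 20.9 per Mb, so the deficit was not particular to chromosome I there, whereas in the replicate lists the ratio to length was 0.58 and 0.43 on chromosome I and 0.85 and 0.76 on chromosome V. Lists that end before its weaker regions stay open as an explanation: chromosome I held 12.6% of the weaker 50% of the combined list (Wilson interval 10.9 to 14.5%), 11.1% of the better 50% and 15.1% of the length, but the bound set in advance, a share below the length, excludes nothing because regions past the q limit are in no list. Shortening the combined list from 2621 to its best 1310 regions moved the ratio to length only from 0.79 to 0.74, against 0.58 for the 1038 regions of replicate 1, so the lower ratios of the replicate lists, which differ in more than length, are no support for it. A higher bar for calling on chromosome I is another candidate, which might arise if the input was scaled per chromosome and the very strong region at its right end raised the scale, though that would not reach chromosome V. At matched width the median −log10 q on chromosome I was lower than on the other autosomes, with a difference of −0.68 (stratified permutation p = 5.00e-04), as this predicts, and taking 0.68 off every region of the other autosomes left 78.7% of them past the limit, short of the observed ratio of 0.70, although a shift measured only on regions past the limit may be too small. Against all other chromosomes the difference was −0.46 in the combined list (adjusted p = 0.032, stratified permutation), and −0.48 in replicate 1 and −0.54 in replicate 2, where it did not pass the test (adjusted p = 0.162 and 0.612, stratified permutation), and weaker binding on this chromosome, which would give the same sign, stays open because no biological explanation was tested. The same test in the combined list also passed for chromosome III (0.28, adjusted p = 0.0438, stratified permutation), IV (0.43, adjusted p = 0.0132, stratified permutation) and X (−0.69, adjusted p = 0.0048, stratified permutation), so such a difference was not particular to chromosome I, and the positive values of III and IV enter the −0.68.

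Regions on the X chromosome were wider than those on the autosomes, with medians of 422.5 and 363 bp in the combined list. The difference was 59.5 bp there (permutation adjusted p = 3.00e-05), 60.5 bp in replicate 1 (permutation adjusted p = 7.50e-04) and 95.5 bp in replicate 2 (permutation adjusted p = 0.00653). The adjustment ran over the lists, which share regions, and not over the choice of X from among the chromosomes. X had the largest median width of any chromosome in each list, so these p-values may be too small. In the combined list the tables argue against lower q-values on X as the cause, since the median −log10 q was 5.49 on X and on the autosomes and the mean width difference within quintiles of −log10 q was 71.0 bp (stratified permutation p = 0.0001), and in replicate 1 the medians were 5.10 and 5.23 and the difference within quintiles 50.8 bp (stratified permutation p = 0.0279). In replicate 2 this cause stays open, since the median −log10 q was 5.95 on X and 5.38 on the autosomes (permutation p = 0.0635) and the difference fell to 43.1 bp within quintiles (stratified permutation p = 0.377), with 38 regions on X. At matched width, −log10 q on X minus the other chromosomes was −0.69 in the combined list (adjusted p = 0.0048, stratified permutation) and −0.05 in replicate 1 (adjusted p = 0.895, stratified permutation), but 1.52 in replicate 2 (adjusted p = 0.0084, stratified permutation). A higher bar for calling on X predicts the negative sign of the combined list, read as for chromosome I, though that value in part restates that X regions were wider at equal q, and the positive sign argues against it in replicate 2. Base composition and binding on X were not tested.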
